A study of Ginkgo biloba with 9 samples.

How the data were processed

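Messenger RNA of Ginkgo biloba leaves was sequenced at 3 dates in 1 autumn: green leaves on September 12, turning leaves on October 26 and yellow leaves on November 8. Per the labels' protocols, the leaves came from 3 healthy adult trees growing outdoors, total RNA was extracted with a plant RNA kit, and libraries followed standard Illumina protocols. Each stage has 3 libraries, numbered 1 to 3 in their titles. The labels do not state that a number marks 1 tree, and the stage cannot be told apart from the calendar date, since each stage was sampled on a single day.

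The deposited table holds raw read counts per gene model, 1 column per library, for 43834 gene models, of which 41840 carry identifiers beginning with Gb_ and the remaining 1994 another prefix. The submitters' processing notes name CASAVA 1.8, HISAT2 2.0.4 and HTSeq 0.6.1, without saying what each was used for. The genome build, the annotation, the strand setting of the counting and any read filter are not given in the sources used here. The values were whole numbers, no line of the table held unassigned reads or a total, and each column name matched a single library title. The authors deposited 1 column per library and no pooled column. No reference, name table or description of the gene models was used here, so identifiers are not paired with gene names and no statement about the function of a gene model is made. For the same reason the 34 pathway, hormone, transcription factor and cell type lists fixed beforehand as name patterns were not tested, and markers of other cell types were not checked. Gene models that share reads with near-identical copies, or that overlap another model, could not be recognised, so a count of any single model carries that uncertainty.

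Library totals ran from 23766331 to 32319325 counts. No pair of libraries within a stage agreed within sampling noise: the chi-square per degree of freedom was between 46.9 and 143, so no library was treated as a repeat of another. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. For a model at 0 counts in all libraries of a stage, the floor was 3 counts over the 3 libraries of that stage, which corresponded to 0.0289 normalized CPM (counts scaled to a common library total) in green and 0.0537 in yellow leaves.

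Counts were analysed in R 4.3.3 with edgeR 4.0.16. Models were kept by filterByExpr with the stage as group (minimum count 10, minimum total 15), which left 23042 models, 21468 of them with Gb_ identifiers and 1574 with the other prefix. Library composition was normalized with TMM (trimmed mean of M values). One quasi-likelihood model (glmQLFit with robust = TRUE, then glmQLFTest) was fitted to all 9 libraries with the stage as the only term and 6 residual degrees of freedom, and gave the 3 pairwise comparisons, an F test over the 3 stages, and a contrast of the turning stage against the midpoint of green and yellow on the log2 scale. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all models tested, and 0.05 was the threshold. Standard errors of log2 fold changes were taken from the fold change and its F statistic. Normalized CPM were counts divided by the TMM-scaled library size. Numbers of detected models and shares of counts were compared over the 3 stages by an exact permutation test of the F statistic over all 1680 assignments of the 9 libraries, whose smallest possible p is 0.00357. An exact permutation test of 3 libraries against 3 cannot go below p = 0.1.

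The tests, the rule for named models and the alternatives were fixed before the data were examined, except where a sentence says otherwise. Without gene names the rule took the 2 models with the largest rise and the 2 with the largest fall in yellow versus green, among those past the threshold, with a mean of at least 10 CPM in the higher stage and with every library of one stage above every library of the other.

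Whether the library numbers pair the samples was checked from the deviations of log2 CPM from the stage means. All 9 pairs of libraries with the same number correlated positively, with r from 0.24 to 0.66 across genes, above the limit of 0.1. Pairs with different numbers gave r from -0.52 to 0.03, and 9 of 9 libraries correlated best with their own number in both other stages. The numbers were therefore read as pairing the libraries, on the data and not on the labels, and values from the model with the replicate number as a block are given where they change a call or move a count by over 1.5 times.

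Alternatives were DESeq2 size factors and upper-quartile factors within edgeR, the DESeq2 1.42.0 Wald and likelihood ratio tests, limma-voom (limma 3.58.1), no filter, a filter of 1 CPM in at least 3 libraries, robust = FALSE, the replicate block, a 2-fold minimum, the 2 compared stages alone, and each library left out in turn. Library totals without a composition factor, the 6 libraries left after removing all those numbered 3, and the block together with DESeq2 size factors were added after seeing the data. For detected models and the share of counts, a permutation of stages within library numbers (216 assignments, smallest p = 0.0278) was added after seeing the data. The detection count without the most abundant models was added in the same way, and so were the abundance classes, the limits for models switched on or off and the group of models with the other prefix.

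The fits were tested on simulated data: negative binomial counts for the 23042 models with the means, library sizes and dispersions of the real libraries, and 200 models changed, each with at least 50 expected counts. For turning versus green and the midpoint test the simulated change was in the turning stage only, and otherwise in the yellow stage only. The midpoint values therefore hold for models that peak or dip at the turning stage. Simulated libraries of the same number were not linked. The edgeR fit recovered 59% of models changed 4-fold and 6% of those changed 2-fold in turning versus green. It recovered 67% and 4% in yellow versus turning, 65% and 5% in yellow versus green, and 76% and 25% in the midpoint test. Its false calls were at most 6.58% of all calls in these comparisons. The DESeq2 Wald test recovered 89% of 4-fold changes in turning versus green, but 36.3% of its calls there were false. The 200 changed models are a far smaller part of those tested than the 24.1% to 62.1% called in the real pairwise comparisons. Recovery and false shares depend on that part, so these values do not carry over to the real calls. In a separate simulation, with 22717 models tested, a share of change of 0.4 at the turning stage came back as a median of 0.41 over 1810 models.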

Results

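Gene expression was measured by RNA sequencing in leaves of Ginkgo biloba, a deciduous gymnosperm whose leaves turn yellow in autumn, to follow leaf senescence and coloration over the season. Leaves were green on September 12, turning on October 26 and yellow on November 8, with 3 libraries per stage and 9 libraries in all. The first interval lasted 44 days and the second 13 days. Total counts per library were 32264081, 23766331 and 27654407 in green leaves, 25078682, 28210121 and 32319325 in turning leaves, and 25466370, 24567903 and 24066509 in yellow leaves, in the order of the library numbers. Of 43834 gene models, 11479 had 0 counts in all 9 libraries and 23042 were tested. P-values measure the spread between these libraries, which the labels trace to 3 trees without saying which library came from which tree.

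The stages were the main axis of difference between the libraries. The first principal component of log2 CPM (counts scaled to a common library total) held 66.0% of the variance and ordered the libraries from green through turning to yellow. The second component held 11.4%, and placed the 3 libraries numbered 3, together with turning library 1, on one side and the other 5 libraries on the other side. Within stages, the biological coefficient of variation from a common dispersion was 0.33 in green, 0.36 in turning and 0.40 in yellow leaves. Expression differed among the 3 stages for 13883 models, 60.3% of those tested (edgeR quasi-likelihood F test, adjusted p below 0.05).

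**Figure D1:**
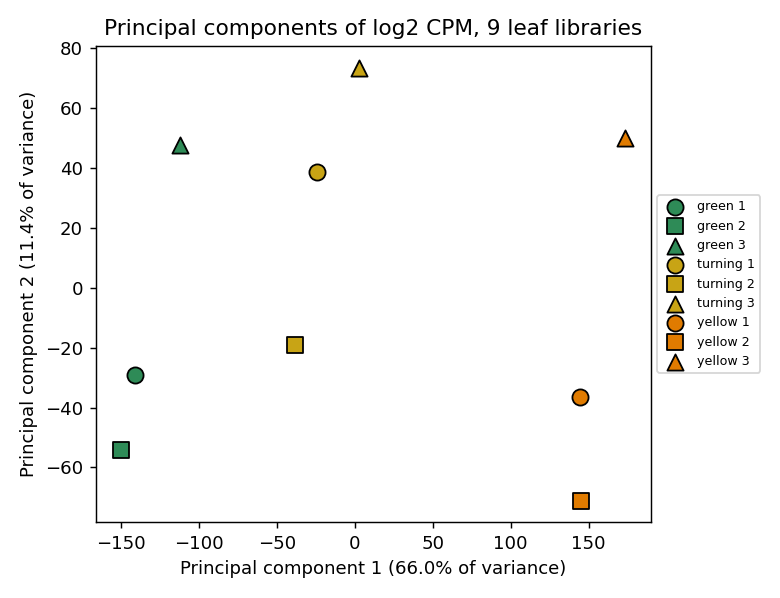
Principal components 1 and 2 of log2 CPM for the 9 libraries, with the stage as colour and the library number as marker shape. Component 1 (66.0% of variance) separates the stages, with turning libraries between -38.4 and 2.58, green libraries at or below -112.1 and yellow libraries at or above 144.4.

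Fewer gene models were detected as the leaves yellowed. The limit of 1 CPM was taken on library totals, without TMM factors. It was reached by 19953 ± 109 models in green leaves, 18776 ± 257 in turning leaves and 17046 ± 41.6 in yellow leaves (mean ± SD, n = 3 libraries each). The stages did not overlap, and the exact permutation test over the 3 stages gave p = 0.00357, the smallest it can give. Each pairwise comparison of 3 with 3 libraries gave the smallest possible exact p of 0.1. The yellow-minus-green difference was -2907 at 1 CPM, -880 for models with at least 1 count, and -725 for models with a count after thinning each library to the smallest total. After thinning, yellow library 2 with 26882 models lay above turning libraries 1 and 3 with 26809 and 26748 (yellow against turning, exact permutation p = 0.3). The concentration measure fixed beforehand was the share of counts in the 100 most abundant models of each library, with 1000 and 10 models as alternatives. The 1000 most abundant models held 49.8% ± 1.72 of the counts in green leaves, 51.3% ± 0.20 in turning leaves and 57.0% ± 1.14 in yellow leaves (SD, n = 3). The exact permutation p was 0.00357, and 0.0278 permuting within library numbers. For 10 models the shares were 7.35%, 6.53% and 7.27% (exact permutation p = 0.464). For the 100 most abundant models the shares were 21.2% ± 1.95, 20.7% ± 0.50 and 24.4% ± 1.87, which did not pass the test over the 3 stages (exact permutation p = 0.0679, and p = 0.111 permuting within library numbers). Yellow libraries lay above green libraries of the same number by 2.31, 3.70 and 3.69 percentage points and above turning libraries by 3.84, 5.08 and 2.08, without overlap between yellow and turning (exact permutation p = 0.1). Leaving out green library 3 or yellow library 3 gave an exact p of 0.0429 for that share.

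**Figure D2:**
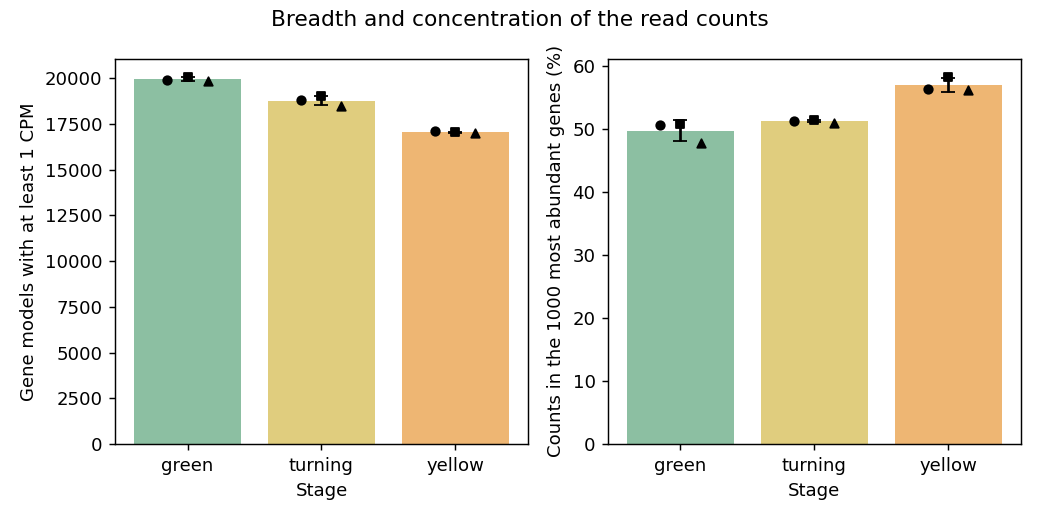
Left, number of gene models with at least 1 CPM per library; right, percentage of counts in the 1000 most abundant models of each library. Bars are stage means, error bars are SD over 3 libraries and points are libraries with the library number as marker; detected models fall from 19953 in green to 17046 in yellow leaves while the share rises from 49.8% to 57.0%.

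Comparison of yellow with green leaves covers the whole season. In yellow leaves 6949 models were higher and 7356 were lower, together 14305 or 62.1% of those tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). At least 4-fold changes were seen for 2561 higher and 3319 lower models. Of the 14305 models, 14254 moved in the same direction in all 3 pairs of same-numbered libraries, as did 81.2% of all tested models, where chance gives 25%. The models were called on these same libraries, so agreement among them is largely set by the call and is no separate support. The balance of higher and lower models depended on the scaling of the libraries, because TMM factors averaged 1.24 in green and 0.75 in yellow leaves. Higher models made up 48.6% of the calls with TMM, 49.8% with DESeq2 size factors, 36.9% with upper-quartile factors and 24.9% with library totals alone. The median log2 fold change of all tested models was -0.06 with TMM, -0.39 with upper-quartile factors and -0.78 with library totals, and directions below are relative to the TMM scale.

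Classes of abundant and scarce models differed in direction between green and yellow leaves. Models were ranked by mean normalized CPM over all libraries and put into 3 classes of equal size, a grouping chosen after the data were examined. That mean includes the yellow libraries, so a rise moves a model towards the abundant class and a fall towards the scarce class. Part of the difference between classes is therefore built in, and how much was not tested. In the most abundant class, above 21.1 CPM, 3814 models were higher and 1603 lower in yellow leaves, with a median log2 fold change of 0.51. In the least abundant class, up to 3.16 CPM, 1145 models were higher and 3077 lower, with a median of -0.79. The middle class had 1990 higher and 2676 lower models and a median of -0.16. With library totals as the scaling the most abundant class turned to 2110 higher and 3104 lower models, with a median of -0.21. Relative to the median of all tested models, the most abundant class stood at 0.57 and the least abundant class at -0.73 with TMM, and at 0.57 and -0.72 with library totals. A change of scaling shifts all models by nearly the same amount, so these relative values could hardly differ and are no check of the pattern.

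The most abundant transcripts were exchanged in part. Of the 100 models with the highest mean CPM in green leaves, 38 were also among the 100 highest in yellow leaves, 67 were shared between green and turning leaves, and 62 between turning and yellow leaves. Each list was chosen on these libraries, so its direction is not independent evidence. Among the 100 leading models of green leaves, 44 were lower, 28 higher and 28 not called in yellow leaves. Among the 100 leading models of yellow leaves, 88 were higher, 1 was lower (2 with the replicate block) and 11 were not called, with a median log2 fold change of 2.36. With library totals the corresponding counts were 60 lower and 14 higher for the green list and 74 higher and 6 lower for the yellow list.

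Among models that met the rule for named models, the 2 largest fitted rises from green to yellow were those of Novel00408 and Novel01229. Both had 0 counts in green leaves, so the size of the fitted rise and its rank depend on the prior count. Novel00408 had 0 counts in all 3 green libraries, 1.001 ± 1.13 normalized CPM in turning leaves and 135 ± 143 CPM in yellow leaves (SD, n = 3). Its mean level in yellow leaves was 4656 times the floor of 3 counts over the green libraries, and 1923 times without yellow library 3. Single yellow libraries ran from 15.7 to 293 CPM (yellow versus green, edgeR adjusted p = 0.00242). Novel00408 was also higher in yellow than in turning leaves, with a log2 fold change of 7.04 ± 1.54 (SE; edgeR adjusted p = 0.0122), which ranged from 5.77 to 8.52 over the alternatives, the lowest without yellow library 3 and the highest without turning library 3. Its 97 counts in turning against 0 in green leaves did not pass the test without the block (edgeR adjusted p = 0.109) and passed it with the replicate block (edgeR adjusted p = 0.00193; 0.00176 to 0.444 over all alternatives). Novel01229 had 0 counts in green leaves, 0.20 ± 0.35 CPM in turning leaves, all from turning library 3, and 117 ± 96.8 CPM in yellow leaves (SD, n = 3). Its mean in yellow leaves was 4041 times the green floor (yellow versus green, edgeR adjusted p = 0.000804) and 2109 times without yellow library 3. Its log2 fold change from turning to yellow was 9.02 ± 1.34 (SE; edgeR adjusted p = 0.00293). That fold change ranged from 8.09 without yellow library 3 to 14.63 without turning library 3, where the turning counts are all 0 and the fitted value depends on the prior count.

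By the same rule the 2 largest fitted falls were those of Gb_25650 and Gb_23362. Both had 0 counts in yellow leaves, so this rank also depends on the prior count. Gb_25650 had 26.2 ± 13.2 normalized CPM in green leaves, 1.03 ± 0.71 in turning leaves and 0 counts in all 3 yellow libraries (SD, n = 3). Its mean in green leaves was 488 times the floor of 3 counts over the yellow libraries. Single green libraries ran from 13.9 to 40.2 CPM (yellow versus green, edgeR adjusted p = 0.000398). Gb_25650 was already lower in turning than in green leaves, with a log2 fold change of -4.68 ± 0.76 (SE; edgeR adjusted p = 0.0102). Gb_23362 had 21.7 ± 8.80 CPM in green leaves, 3.86 ± 4.44 in turning leaves and 0 counts in yellow leaves (SD, n = 3). Its mean in green leaves was 404 times the same floor (yellow versus green, edgeR adjusted p = 0.00127). Its log2 fold change from green to turning was -2.49 ± 0.87 (SE), which did not pass without the block (edgeR adjusted p = 0.083) and passed with it (-2.99 ± 0.56, edgeR adjusted p = 0.016) and without turning library 2 (-4.03 ± 0.55, edgeR adjusted p = 0.0152). Over all alternatives the adjusted p of that comparison ran from 0.0109 to 0.207. Gb_25650 and Gb_23362 were both lower in yellow than in turning leaves (edgeR adjusted p = 0.0118 and 0.00811). With limma-voom the call of Gb_25650 from turning to yellow was lost (adjusted p = 0.0611; 7.95e-06 to 0.0611 over all alternatives).

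**Figure D3:**
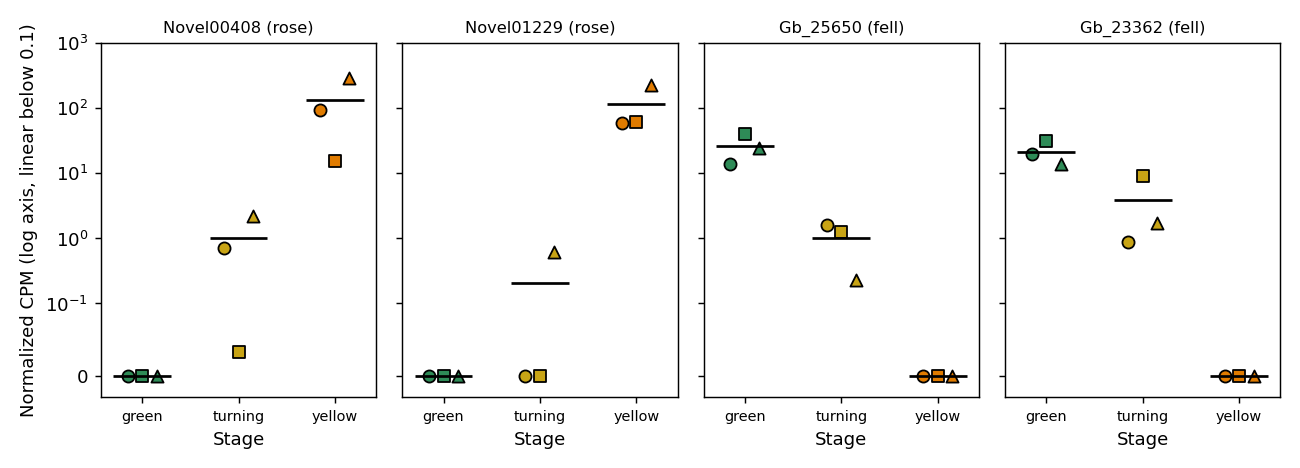
Normalized CPM of the 4 named gene models in each library, on an axis that is logarithmic above 0.1 and linear below; horizontal lines are stage means and marker shape is the library number. Novel00408 and Novel01229 are at 0 in the green libraries and average 135 and 117 CPM in yellow leaves, and Gb_25650 and Gb_23362 average 26.2 and 21.7 CPM in green leaves and are at 0 in the yellow libraries.

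Comparison of turning with green leaves covers the first interval. In turning leaves 2713 models were higher and 2843 lower, together 5556 or 24.1% of those tested (edgeR, adjusted p below 0.05). All 5556 moved in the same direction in the 3 same-numbered pairs, as did 70.003% of all tested models, where chance gives 25%. Agreement among called models is largely set by the call on these same libraries. At least 4-fold changes were seen for 446 higher and 527 lower models. In the most abundant class 1856 models were higher and 503 lower, with a median log2 fold change of 0.25. In the least abundant class 228 were higher and 1315 lower, with a median of -0.43. Membership of these classes rests on a mean that includes the turning libraries, so it depends in part on the change itself. With the replicate block these classes had 2532 higher and 771 lower, and 429 higher and 2041 lower models. With library totals the most abundant class had 1101 higher and 951 lower models and the least abundant class 171 higher and 1813 lower, with medians of 0.04 and -0.64, and that of all tested models moved from -0.02 to -0.23. With the replicate block, 4050 models were higher and 4439 lower, together 8489, and 5545 models were called in both fits. Leaving out any 1 library of the compared stages, which leaves 2 in that stage, lowered the number. It was 2190, 1971 and 4851 without green library 1, 2 or 3. Without turning library 1, 2 or 3 it was 3359, 3648 and 2528. Higher models made up 48.8% of the calls with TMM, 35.0% with upper-quartile factors and 27.1% with library totals.

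Comparison of yellow with turning leaves covers the second interval. In yellow leaves 4717 models were higher and 4843 lower than in turning leaves, together 9560 or 41.5% of those tested (edgeR, adjusted p below 0.05). Of these, 9514 moved in the same direction in all 3 same-numbered pairs, as did 69.97% of all tested models. Agreement among called models is again largely set by the call. At least 4-fold changes were seen for 1228 higher and 1210 lower models. In the most abundant class 2632 models were higher and 1262 lower, with a median log2 fold change of 0.24. In the least abundant class 773 were higher and 1675 lower, with a median of -0.40. Here too the class of a model depends in part on the change, since the ranking mean includes the yellow libraries. With library totals the most abundant class turned to 1244 higher and 2774 lower models and a median of -0.26, and the median of all tested models moved from -0.05 to -0.56. Higher models made up 49.3% of the calls with TMM, 37.0% with upper-quartile factors and 20.9% with library totals.

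**Figure D4:**
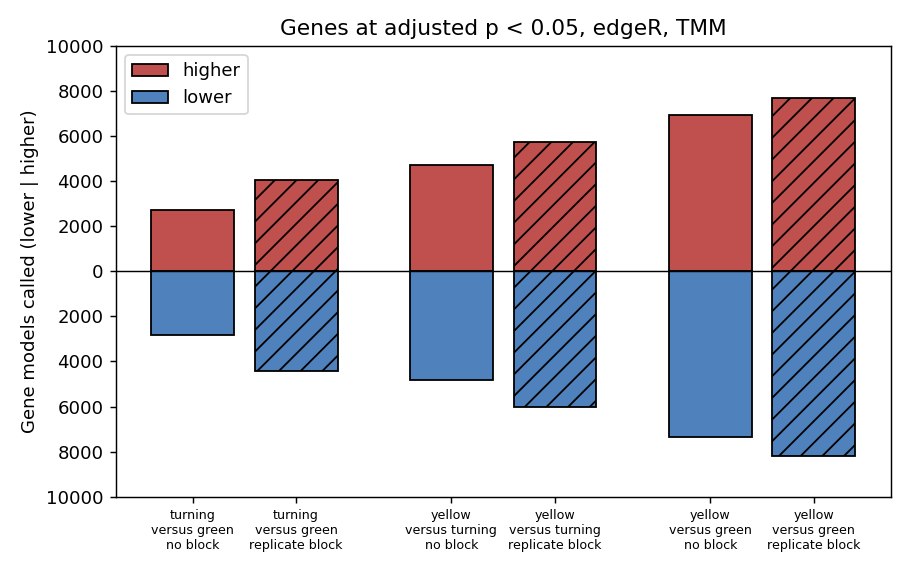
Number of gene models called higher (above the zero line) and lower (below it) in each comparison at an adjusted p below 0.05, edgeR with TMM; plain bars are the fit without a block and hatched bars the fit with the replicate number as a block. The counts without a block are 5556 for turning versus green, 9560 for yellow versus turning and 14305 for yellow versus green.

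Most models called in both intervals moved the same way in both. A rise in both intervals was called for 1537 models and a fall in both for 1577. A further 3054 models rose and 3129 fell from turning to yellow without a call in the first interval, and 1039 rose and 1140 fell from green to turning without a call in the second. A missing call does not show that a model stayed level. A rise to the turning stage followed by a fall was called for 137 models and a fall followed by a rise for 126. With the replicate block the counts were 2304 and 2511 for the same direction in both intervals, and 286 and 290 for the opposite directions. Leaving out 1 library at a time gave 660 to 1508 models rising in both intervals, 551 to 1586 falling in both, 55 to 147 rising and then falling, and 47 to 125 falling and then rising. With green 1, green 2, turning 1, turning 2 and turning 3 left out, in that order, 727, 660, 1020, 927 and 785 models rose in both intervals, and 603, 551, 808, 840 and 609 fell in both. In the same order 62, 55, 73, 76 and 87 rose and then fell, and 47, 50, 57, 60 and 54 fell and then rose.

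The turning libraries enter both intervals, which by itself turns their fold changes against each other. Across genes, which are not independent replicates, the log2 fold changes of the intervals correlated with r = 0.42, against -0.49 in 100 simulated series with no change. Their covariance was 0.53 against -0.12 in the simulation, a difference of 0.65. Independent lists of the same lengths would share 555 models rising in both intervals and 598 falling in both, and 570 and 582 with opposite directions. The 3 turning libraries cannot be split into parts of at least 2.

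At the turning stage, 0.40 of the log2 change between green and yellow had been reached. This share is the median over the 11060 models with at least a 2-fold difference between yellow and green leaves, with quartiles of 0.26 and 0.55, and 67.6% of these models had a share under 0.5. It was 0.41 for the 5134 rising and 0.40 for the 5926 falling models, and 0.40, 0.39 and 0.42 within library numbers 1, 2 and 3. The turning stage differed from the midpoint of green and yellow for 607 models, 359 above it and 248 below it (edgeR, adjusted p below 0.05). Those above it made up 59.1% with TMM, 83.2% with library totals and 46.5% of the calls of the DESeq2 test. Of the 607 models, 177 were higher in yellow than in green leaves and lay below the midpoint at the turning stage, and 224 were lower in yellow leaves and lay above it. With the replicate block 2245 models differed from the midpoint, 1146 above it and 1099 below it, with 762 and 707 models in the 2 classes just named. The number without the block fell with any 1 library left out. It was 93, 83 and 253 without green library 1, 2 or 3, and 49, 10 and 62 without turning library 1, 2 or 3. Without yellow library 1, 2 or 3 it was 487, 141 and 558.

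**Figure D5:**
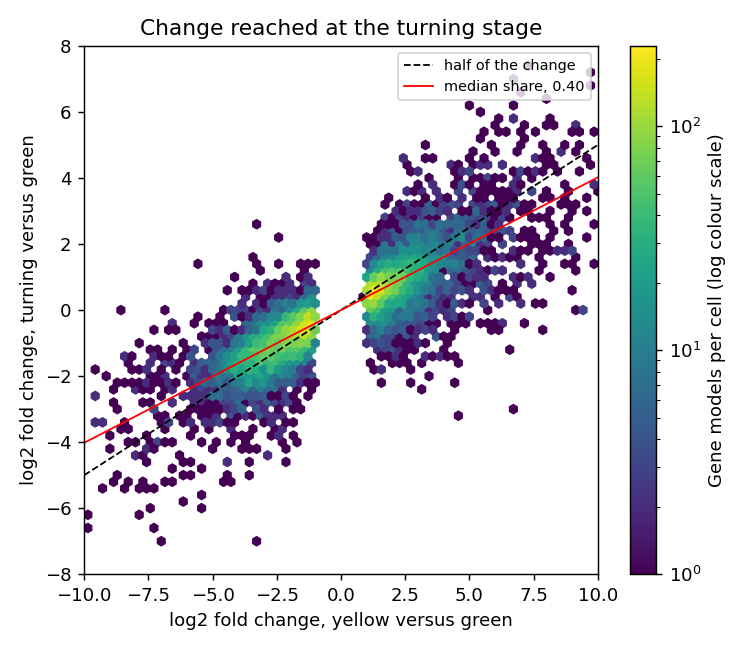
Log2 fold change of turning versus green leaves (y axis) against yellow versus green leaves (x axis) for the models with at least a 2-fold difference between yellow and green, as a density with a logarithmic colour scale; 45 of the 11060 models lie outside the axes. The red line is the median share of 0.40 and the dashed line a share of 0.5, and both rising and falling models spread around the red line.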

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

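The test on models with opposite changes in the 2 intervals was chosen after its result was seen.

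For 607 models the change from green to turning differed from the change from turning to yellow by a direct test of the difference (the midpoint contrast, edgeR, adjusted p below 0.05). Among 60 splits of the 9 libraries into 3 groups of 3, the real one included, 3 gave at least as many models. This share does not decide whether chance gives such a count, since the 2 splits besides the real one hold stage differences. The splits were fitted without the replicate block, with which the real count was 2245, and were not repeated with it. The 2 others called several times the real count, which points to a structure of the samples: the highest, with 6027 models, kept the 3 yellow libraries together as a group, and the next, with 5675, the 3 green libraries. These 2 splits therefore hold real stage differences and are no measure of chance. Every other drawn split gave at most 11 models, including one that kept the yellow libraries together and gave 4. All splits besides the real one mix stages within groups, which adds stage differences to their spread and can lower their calls.

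A candidate explanation for the intermediate levels of turning leaves is a mixture of unchanged green and yellow tissue, which has 1 mixing share for all models on the linear CPM scale. Among models with at least 4-fold change between green and yellow, the median linear share was 0.22 for 2561 rising and 0.70 for 3319 falling models, computed from stage means. The falling share exceeded the rising share by 0.497 ± 0.043 on average over the 3 library numbers (SD, n = 3), which argues against a mixture of unchanged tissue as the whole cause of the intermediate levels. A mixture also cannot place a model outside the range of its parts. Opposite directions in the 2 intervals, with both changes over 2-fold, were called for 130 models. The count was 235 with the replicate block and 63 to 149 when 1 library at a time was left out. It was 67 without green library 1, 63 without green library 2, 84 without turning library 1 and 83 without turning library 2. The turning libraries enter both intervals, which by itself favours opposite changes, and no count expected from that alone was computed. These models are therefore not used for or against a mixture. A mixture of tissues that had also changed, and a turning stage with expression of its own, stay open and were not tested.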

How the results depend on the processing

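Library totals, the fits without the libraries numbered 3, the block with DESeq2 size factors, the permutation within library numbers and the detection count without the most abundant models were chosen after seeing the data. Of 22 alternatives tried for each pairwise count, those for yellow versus green (11060 to 15941 models) and yellow versus turning (6423 to 11737) stayed within 1.5 times the reported number, as did the F test over 3 stages (11893 to 16071). Turning versus green moved to 8489 models with the replicate block, 8487 with the block and DESeq2 size factors, 3426 with a 2-fold minimum, and 1971 to 6139 when 1 library at a time was left out. The midpoint count moved to 2245 with the replicate block, 2265 with the block and DESeq2 size factors, 2536 with the DESeq2 test, 1362 with library totals, 318 with a 2-fold minimum and 10 to 558 with 1 library left out. Without the 3 libraries numbered 3 it was 0 in edgeR (5058 models at an unadjusted p below 0.05). A fold minimum lowers a count by construction. Fewer libraries leave fewer degrees of freedom, and a library left out of a compared stage also leaves that stage with 2 libraries. Turning versus green gave 1971 to 4851 models without 1 green or turning library. It gave 5312 to 6139 without 1 yellow library, where both compared stages kept all their libraries. The cause of the shifts, apart from the fold minimum, was not tested. The median share of change was 0.376 with library totals and 0.364 to 0.431 with 1 library left out. The yellow-minus-green difference in the share of counts was 3.23 percentage points for 100 models, -0.0832 for 10 models, 7.23 for 1000 models and 2.13 to 4.10 with 1 library left out. The difference in detected models, -2907 as reported, was -725 for models with a count after thinning to the smallest library, -2544 at 5 CPM, -2631 without the most abundant models, -2953 to -2846.5 with 1 library left out and -2934.5 without the libraries numbered 3, where 2 libraries per stage cannot give an exact p under 0.0667. All 4 named models kept their direction and call in yellow versus green under 21 alternatives each. In the other comparisons, Gb_25650 lost its call from turning to yellow under 1 alternative, limma-voom, and Gb_23362 and Novel00408 gained one from green to turning under 5 and 3. The replicate block changed no other call. The gene list alternatives were not run, since no list could be matched to identifiers. Depth limits what can be said of models at 0 counts in a stage, whose floor was 0.0289 CPM in green and 0.0537 CPM in yellow leaves.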

Other observations

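The tests on models missing from or confined to 1 library number were chosen after their results were seen, and the detection count without the most abundant models was added after seeing the data.

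Some models were switched nearly on or off over the season, by limits on normalized CPM set after seeing the data. Under 1 CPM in every green library and at least 10 CPM in every yellow library were 73 models, and the reverse held for 27. In the first interval 3 models went on and 1 off by these limits. In the second interval 15 models went from under 1 CPM in every turning library to at least 10 CPM in every yellow library. In that interval 0 went the other way. TMM factors averaged 1.24 in green, 1.07 in turning and 0.75 in yellow leaves, so the limits stand for fewer counts per library total in yellow leaves. Compared with library totals this scaling favours models going on over models going off. These numbers were not counted with library totals. Models without a Gb_ identifier held 3.15% of the counts in green, 3.47% in turning and 3.99% in yellow leaves. Of the 1574 such models tested, 470 were higher and 335 lower in yellow than in green leaves, 51.1% called against 62.9% of Gb_ models. As a set they did not differ from the other models in direction at the threshold (camera adjusted p = 0.315 with a preset correlation, and adjusted p = 0.408 with an estimated correlation), with medians of the log2 fold change of 0.18 and -0.08.

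The most abundant model over all libraries was Gb_06050, singled out after its values were seen. Its normalized CPM were 18286, 25287 and 5959 in green libraries 1, 2 and 3, 14930, 16000 and 6443 in turning libraries, and 18822, 17627 and 2539 in yellow libraries. No comparison of 2 stages called Gb_06050 in the fit without the block (edgeR adjusted p = 0.726, 0.957 and 0.71). In the blocked fit its level differed between library numbers (edgeR adjusted p = 0.0323). Without the block, differences between numbers enter the spread of the stage comparisons (SE of 0.76 on the log2 scale in each). The missing calls therefore do not show a constant level.

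Fewer models were detected in yellow leaves, for which a few very abundant models and smaller libraries were weighed. The 171 models among the 100 most abundant of any stage were removed. The yellow-minus-green difference in models with at least 1 CPM was then still -2631. Over the 3 stages the exact permutation p was 0.00357, and 0.0278 permuting within library numbers. This argues against these 171 models as the whole cause. The 1000 most abundant models held 57.0% of the counts in yellow and 49.8% in green leaves. The 1 CPM limit was set on library totals, so this wider concentration stays open as a contribution. After thinning each library to 23766331 counts the number of models with a count still differed among stages (exact permutation p = 0.0143, and p = 0.0278 permuting within library numbers). The highest yellow library, with 26882 models, lay below the lowest green library, with 27034, which argues against library size as the whole cause. That difference was -725, against -880 for models with a count before thinning, and turning and yellow libraries overlapped, with 26809 and 26748 models in turning libraries 1 and 3 (yellow against turning, exact permutation p = 0.3). RNA quality in senescing leaves and a narrower set of transcribed genes stay open and were not tested.

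Library numbers were linked to expression in 1568 models, 6.80% of those tested (edgeR F test of the numbers in the blocked fit, adjusted p below 0.05), and 1170 of them also differed among the stages. Of 36 relabellings of the numbers within stages, 1, the real one, gave as many and the highest other gave 81. That is the smallest share 36 relabellings can give. It lies under 0.05 but does not exclude chance. Gb_24787 and Gb_13269, named after their values were seen, were the 2 models nearly missing in a single number (at most 3 counts in its 3 libraries, at least 5 CPM in the other 6), and Novel00038 was the 1 model found in a single number, against at most 1 of either kind in other relabellings. These counts are too small to tell whether reads from another organism in some libraries contribute. Differences between trees may underlie the numbers and cannot be told apart from a shared day of extraction or library preparation, since the labels tie the numbers to neither.

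For the pairwise comparisons, 1 of 10 splits of the 6 libraries, the real one, gave as many called models in each case, and 10 splits are too few for a share under 0.05. The real counts were 5556, 9560 and 14305 for turning versus green, yellow versus turning and yellow versus green. The highest other split gave 0 in edgeR in each. Every other split puts libraries of both stages in each group, so stage differences enter its spread and lower its calls. Its count is therefore not what libraries without a stage difference would give. The 3 other splits that also part all 3 same-numbered pairs gave at most 232, 736 and 346 models at an unadjusted p below 0.05, and the splits that part 1 pair gave up to 2122, 1410 and 702. For the F test over 3 stages, 1 of 60 splits of the 9 libraries, the real one, gave as many as 13883 models. The highest other, which kept the 3 yellow libraries together, gave 9097. The share is the smallest that 60 splits can give, and the splits moved libraries freely across library numbers. The splits besides the real one also mixed stages within groups, which adds stage differences to their spread. It lies under 0.05 but does not exclude chance.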
